A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

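RNA levels were measured on 2-colour spotted arrays in Halobacterium salinarum NRC-1, a salt-loving archaeon, from a strain lacking ura3 and boa1. Per the labels, 4 RNA samples were each hybridised on 2 arrays with the dyes exchanged, 8 arrays in all. In every hybridisation the other dye carried a common reference RNA from a mid-log NRC-1 culture. On replicate 1 of each sample the strain's RNA was in Alexa 532 and the reference in Alexa 647, and on replicate 2 the dyes were exchanged.

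The deposited scanner tables hold the intensity of each of 10752 spots on a linear scale. Per the file headers, each dye was scanned at 2 settings, H and L, and each setting has a mean spot intensity and a median background intensity from the spot's surroundings. The image program is not given in the sources used here, and the labelling protocol refers to an earlier publication. The authors' value table holds log10 ratios whose scale, centring and direction are not stated, so it was set against the scanner values of the same arrays. Its rows run across the whole array and those of the scanner tables run block by block. Matched by place on the array, the table correlated with log10 of Alexa 532 over Alexa 647 from the H scan at r = 0.810 to 0.968, and matched by row number at 0.111 to 0.280. Over spots below an H-scan intensity of 40000, 97.0% to 99.97% of the values lay within 0.001 of that ratio plus 1 constant per array, which ran from 0.107 to 0.342. The value table is thus Alexa 532 over Alexa 647 on every array whatever the dye exchange, without background subtraction. The medians of its columns ran from 0.0142 to 0.0620, and how the authors chose the constant stays unknown.

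From the scanner tables, a dye's H-scan intensity above 40000 was replaced by the L-scan intensity, rescaled by the median ratio of both scans over spots between 10000 and 30000. This touched 190 to 317 spots per array in Alexa 532 and 435 to 786 in Alexa 647. Background was corrected with normexp at an offset of 50 and each array was normalized by global loess in limma 3.58.1 under R 4.3.3. Ratios were turned to strain over reference on every array and expressed as log2. The 10752 spots are 2688 features of 4 spots each, which were averaged. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.

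Gene names came from the platform annotation, which names 1 gene for each of 532 probes, several for 0, and leaves 10220 probes unnamed here. This gives 133 named features, so gene names cover only a small part of the array. The gene table of the reference assembly given with the data shares 0 gene identifiers with the annotation, so symbols were kept as annotated and no coordinates are given. boa1, its relatives boa2 to boa4 and bop are not among the named features. A feature was called above background in a channel when its mean signal over background was at least 50% of the background. By this measure 964 to 1520 features per array and channel were above background, 952 features were so in the strain's channel on all 8 arrays and 1063 on none. The number of arrays and this signal limit the precision.

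The 2 arrays of a sample are technical copies and were averaged to 1 value. A 2 by 2 additive model with oxygen and light as terms was fitted to the 4 samples with limma (lmFit and eBayes), leaving 1 residual degree of freedom, and gave the oxygen effect (high minus low), the light effect (light minus dark) and the mean against the reference. Tests were two-sided with Benjamini-Hochberg adjustment over all 2688 features at 0.05. With 1 RNA sample per combination of oxygen and light, p-values set each effect against the departure from additivity, moderated across features. An interaction would thus enter the error term, and the spread between independent cultures is unknown. The interaction has no residual degree of freedom and is given as values. The test against the reference leaves out the reference's own spread and mixes the deletions with differences in growth. Each SE is limma's moderated one, and each SD is over the 4 samples.

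The comparisons, 24 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. Of the lists, 8 had 3 or more named genes and were tested with camera at a preset correlation of 0.01 among the 133 named genes. Another 7 had no named gene, and 55 named genes were in no list. The test of the lists on the mean against the reference was added after the data were seen. By the rule, the oxygen and light comparisons name up to 10 genes per direction past the threshold with the same sign in all 4 differences between arrays of equal dye orientation, filled up to 5 with genes that did not pass. The comparison with the reference names the 10 highest and 10 lowest genes past the threshold with the same sign on all 8 arrays. Lists past the threshold, or with 2 or more members past it, add up to 4 members with the largest differences, and pyrF (the symbol used for ura3 here), boa1 to boa4, bat and bop were always named where measured. Other members of the fixed lists were named as examples after their values were seen. Transposases and control spots were not named as changed genes.

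The steps were tested on simulated spots with a dye curve, feature-specific dye effects and the real backgrounds, over 2688 features with 50 changed at each size. For the oxygen comparison, 47 of 50 features with a log2 difference of 2 were recovered, 23 of 50 with 1, 1 of 50 with 0.5 and 0 of 50 with 0.25, with 3 of 2468 unchanged features called. For the mean against the reference, 49 of 50 were recovered at 2 and at 1, 36 at 0.5 and 4 at 0.25, with 7 of 2468 unchanged features called. Alternatives covered background subtraction, normalization within arrays, the value table, dim features, averaging of spots, the variance prior, arrays as units, dye orientations, left-out arrays and samples, thresholds and gene list tests.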

Results

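The series measured transcripts of Halobacterium salinarum NRC-1 lacking boa1 and ura3 in 4 cultures that combined high or low oxygen with light or dark. Cultures of 50 mL were grown in flasks of 125 mL to mid-log phase, shaken at 210 rpm for high oxygen and at 100 rpm for low oxygen, and the dark cultures were kept in painted flasks. Each combination was 1 RNA sample on 2 dye-exchanged arrays against the same NRC-1 reference RNA. Across the 8 arrays the median spot intensity ran from 2116.7 to 4552.9 in Alexa 532 and from 2467.1 to 5553.6 in Alexa 647, against median backgrounds of 1450 to 3408 and 1859 to 4430.5. Log ratios of the 2 arrays of a sample correlated across features at r = 0.17 to 0.32, and at 0.46 to 0.56 among the 672 brightest features. Features are not independent replicates. The spread of dye effects over features had an SD of 0.15 in log2, against 0.20 for the mean of the strain over the reference.

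The deleted genes were looked at first. pyrF, which encodes orotidine 5-phosphate decarboxylase and is the gene removed as ura3, was lower than the reference on 8 of 8 arrays, with a mean log2 ratio of -0.51 ± 0.26 (SD, n = 4 samples). The 4 samples stood at -0.83 in high oxygen and light, -0.20 in high oxygen and dark, -0.42 in low oxygen and light and -0.57 in low oxygen and dark. It missed the threshold in limma with an adjusted p of 0.0723. Its signal was above background on 0 of 8 arrays in the strain's channel and on 1 of 8 in the reference's, so these log2 ratios give no measure of the fold, and whether its probe lies in the deleted part is not known here. boa1 is not among the named features, so its deletion was not checked. bat, the activator of the bacteriorhodopsin gene to which the boa genes are related, had a log2 ratio of 0.065 ± 0.14 (SD, n = 4) and was above background on 0 arrays in either channel.

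The comparison of the strain with the reference asks which transcripts set the boa1 and ura3 deletion strain apart from the wild-type reference, whatever the oxygen and light. Both measured genes of arginine fermentation were higher in the strain. arcC, the carbamate kinase of arginine fermentation, stood at a log2 ratio of 0.51 ± 0.13 (SD, n = 4 samples), or 1.42-fold, and arcA, the arginine deiminase of the same pathway, at 0.27 ± 0.14. argH, the argininosuccinate lyase of arginine synthesis, stood at 0.48 ± 0.064. Lower in the strain were the large-subunit ribosomal proteins rpmC, at -0.75 ± 0.041, and rpl12p, at -0.72 ± 0.065, and the succinyl-CoA synthetase genes sucC, at -0.46 ± 0.12, and sucD, at -0.32 ± 0.075. The adjusted p in limma was 0.0293 for arcC, argH, rpmC, rpl12p and sucC, 0.0347 for sucD and 0.0453 for arcA. arcA was higher on 7 of 8 arrays, and the other 6 had the same sign on 8 of 8. The arcA call held in 14 of 25 alternatives, those of arcC, rpmC, rpl12p and sucC in 22 of 25.

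Arginine fermentation had 2 measured genes, arcA and arcC, and both were higher. Both also passed when adjusted over the list alone, but after passing over all features they could not fail there. Of the TCA cycle list, 5 of 9 genes were lower past the threshold, 6 when adjusted over the list alone. They were sucC, sucD and the glutamate dehydrogenase genes gdhB (-0.33 ± 0.082), gdhA2 (-0.28 ± 0.054, above background on 1 of 8 arrays in the strain's channel) and gdhA1 (-0.24 ± 0.14), enzymes that join the cycle to amino acid metabolism. gdhA1 was above the reference on 3 of 8 arrays, and its call held in 14 of 25 alternatives, with values from -0.45 to -0.029. Over the alternatives gdhB ran from -0.47 to -0.13 and gdhA2 from -0.435 to -0.13. The rest of the list did not pass, with citZ, citrate synthase, at -0.22, mdh, malate dehydrogenase, at -0.15, icd, isocitrate dehydrogenase, at -0.080 and sdhC, a succinate dehydrogenase subunit, at 0.041, which turned negative in the authors' value table. The list's median was -0.24, and camera with the preset correlation gave an adjusted p of 0.0215 over 8 lists, against an adjusted p of 0.627 with an estimated correlation. The estimated correlation of this list was 0. With 1 residual per gene it reflects only the signs of the residuals, so it cannot check the preset 0.01. With an estimated correlation camera rests on the 1 residual degree of freedom, so hardly any list could pass and its outcome decides nothing. The list did not pass fry, which does not compare a list with other genes (adjusted p = 0.153).

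In the motility and chemotaxis list, 10 of 11 genes had positive log2 ratios, with a median of 0.11, and 1 passed the threshold, 2 when adjusted over the list alone. camera gave an adjusted p of 0.00408 with the preset correlation and an adjusted p of 0.627 with an estimated correlation. The latter again rests on 1 residual degree of freedom. From the authors' values, 9 of the 11 were positive. The gene that passed was htr4, a transducer gene, which was higher on 8 of 8 arrays but above background on 0 in either channel, so no fold is given. The response regulator gene cheY, at 0.18, and the sensory rhodopsin transducer gene htr1, at 0.13, had positive ratios on 8 of 8 arrays and missed the threshold.

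The cobalamin synthesis list had 4 genes, all with negative log2 ratios. cbiT, a methyltransferase of the corrin ring, was lower at -0.38 ± 0.11, 2 members passed when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.303). The nucleotide synthesis list had 1 of 12 genes past the threshold, 3 when adjusted over the list alone. This was purL, a purine synthesis enzyme, at -0.32 ± 0.12. The list also holds the deleted pyrF and purB, each above background on 0 arrays in the strain's channel. In the amino acid synthesis list argH was higher and lysS, lysyl-tRNA synthetase, was lower at -0.38 ± 0.12, and 2 of 18 passed also when adjusted over the list alone. The pattern of symbols behind this list had also taken in 6 aminoacyl-tRNA synthetase genes, lysS among them. Of the phototrophy genes 0 of 4 passed, also when adjusted over the list alone, with sop1 and sop2, the sensory rhodopsins, at 0.14 and -0.067, hop, halorhodopsin, at 0.12 (above background on 4 of 8 arrays in the strain's channel), and bat as above. Further genes past the threshold outside these lists were pan1, a proteasome-activating nucleotidase, higher at 0.34 ± 0.13, and, lower, gyrA, DNA gyrase subunit A, at -0.34 ± 0.12, and speB, agmatinase, at -0.30 ± 0.050. Outside the naming rule, and named after their values were seen, secY, the protein translocation channel, at -0.27, and phoU, a phosphate uptake regulator and the single member of its list, at -0.26, were lower too, as was gdhA1 above. Over the alternatives secY ran from -0.40 to -0.11 and phoU from -0.39 to -0.13. gatC also passed, with both channels below background on all arrays. rpl12p was the single member of the ribosomal protein list. The chaperone and proteasome list had 0 of 5 genes past the threshold, also when adjusted over the list alone. camera gave it an adjusted p of 0.895. The DNA repair list had 0 of 4, 2 when adjusted over the list alone, and an adjusted p of 0.776 in camera. Passes within 1 list alone say little here, since 1063 of 2688 features had an unadjusted limma p under 0.05 against the reference.

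Over the whole array, 401 of 2688 features differed from the reference at an adjusted p of 0.05 in limma, 222 higher and 179 lower. Of these, 279 had the same sign on all 8 arrays, 155 higher and 124 lower. Among the 133 named genes 5 were higher and 15 lower. The differences were small, with 1 feature at least 2-fold higher and 2 at least 2-fold lower. At an unadjusted limma p under 0.05 there were 1063 of 2688 features, against 134.4 by chance. This test leaves out the reference's own spread. Among unnamed features above background, those with the largest ratios were probe 1605, at 1.24 ± 0.083 or 2.37-fold, and probe 4845, at 0.97 ± 0.045, and the lowest was probe 1007, at -0.88 ± 0.12. The count rested on single arrays. It was 0 without high oxygen dark replicate 1, 0 without low oxygen dark replicate 1, 145 without high oxygen light replicate 1 and 608 without low oxygen dark replicate 2, and it was 0 from the 4 arrays with the strain in Alexa 647 alone. The smallest adjusted p in limma from all arrays was 0.0293, so the count could fall to 0 with little change in the ratios. Over 25 alternatives arcC ran from 0.38 to 0.61 and rpmC from -0.81 to -0.66, while gdhA1 ran from -0.45 to -0.029.

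**Figure D1:**
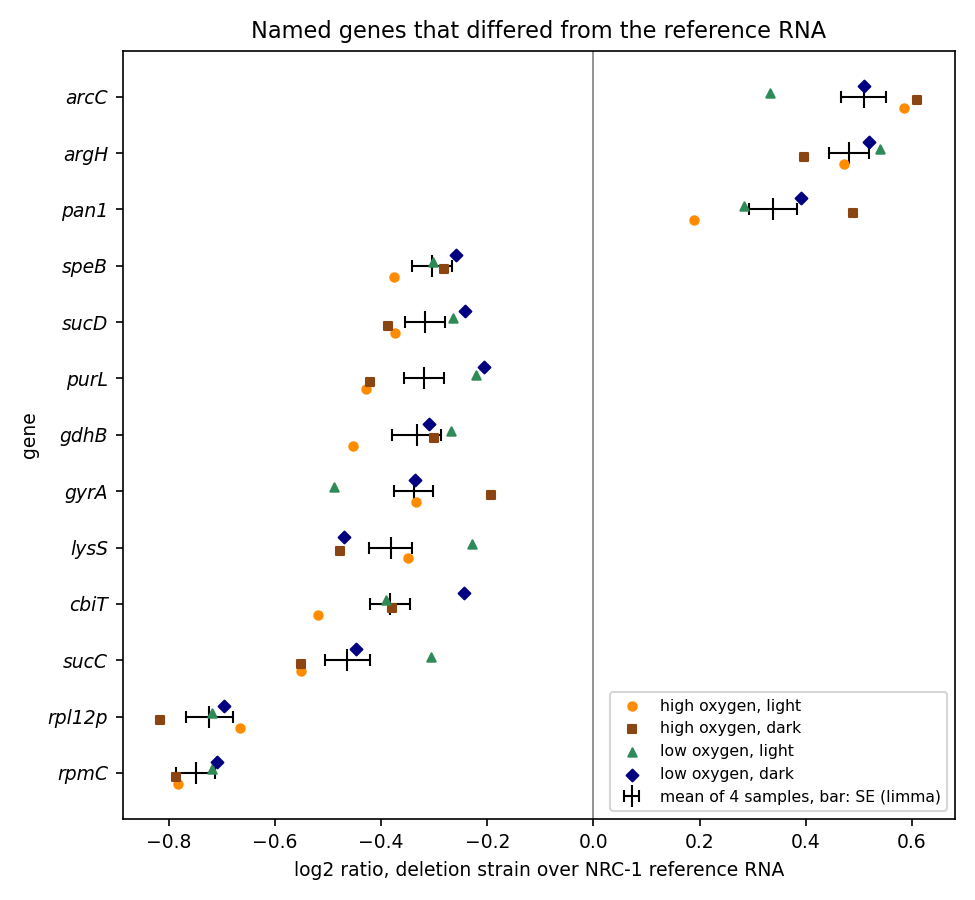
Log2 ratio of the deletion strain over the reference RNA (horizontal axis) for 13 named genes (vertical axis) past the threshold with the same sign on all 8 arrays, leaving out htr4, which was below background. Points are the 4 RNA samples, each the mean of 2 arrays, and black bars are the mean with its moderated SE. arcC, argH and pan1 lie above 0 in all 4 samples, and rpmC and rpl12p lie farthest below, at means of -0.75 and -0.72.

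The oxygen comparison asks which transcripts of the deletion strain follow the oxygen supply. Among named genes above background with the same sign in all 4 differences between arrays of equal dye orientation, carB, the large subunit of carbamoyl-phosphate synthase, had the lowest value in high against low oxygen, with a log2 difference of -0.31 (SE 0.10), from a mean of 0.011 over the reference in low oxygen to -0.30 in high oxygen. serS, seryl-tRNA synthetase, followed at -0.29 (SE 0.076), glmS, an enzyme of glucosamine synthesis, at -0.27 (SE 0.081) and purL at -0.21 (SE 0.074). arcA had the highest value of these genes at 0.23 (SE 0.083), from 0.15 in low to 0.38 in high oxygen, followed by pheS, phenylalanyl-tRNA synthetase, at 0.17, gyrA at 0.15 and cca, the enzyme that adds the CCA end to tRNA, at 0.12. All 8 missed the threshold, with limma adjusted p of 0.484 to 0.585. Of them, pheS and cca were above background on 7 of 8 arrays in the strain's channel.

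By gene list, arcA and arcC, at 0.23 and 0.18, were the 2 arginine fermentation genes, and 0 of 2 passed, also when adjusted over the list alone. In the nucleotide synthesis list 9 of 12 differences were negative, with a median of -0.064, and in the amino acid synthesis list 13 of 18, with a median of -0.072. The 9 include the deleted pyrF and purB, both below background in the strain's channel on all arrays. In the TCA cycle list 6 of 9 were negative and in the motility and chemotaxis list 8 of 11. The phototrophy genes gave 3 positive values of 4, the cobalamin genes 1 of 4, the chaperone and proteasome genes 1 of 5 and the DNA repair genes 1 of 4. In each of these lists 0 members passed, also when adjusted over the list alone, and camera gave adjusted p of 0.780 for all 8 lists. mamA and moaA, which the naming rule also picked, were below background in the strain's channel on all arrays and are given no value.

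Over the whole array, 0 of 2688 features passed for oxygen in limma, with a smallest adjusted p of 0.484. At an unadjusted p under 0.05 there were 264, against 134.4 by chance, 9 of them named genes. On simulated data of this size 23 of 50 features with a log2 difference of 1 were found and 1 of 50 with 0.5, so differences as small as those of carB and arcA were not detectable here. Among unnamed features above background, probe 3453 had a log2 difference of -0.78 (SE 0.10), from 0.71 in low to -0.074 in high oxygen, and probe 3887 one of 0.70 (SE 0.27), from -0.050 in low to 0.65 in high oxygen. The authors' value table gave 117 features for oxygen, among them carB, serS, glmS, the glutamate dehydrogenase gene gdhA1 and the serine hydroxymethyltransferase gene glyA, all lower in high oxygen, and the dim mamA. The array numbers in the labels put the 4 high oxygen arrays before the 4 low oxygen arrays, so array order and oxygen cannot be told apart.

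The light comparison asks which transcripts of the deletion strain follow illumination. Among named genes above background with the same sign in all 4 differences of equal dye orientation, psmA, a proteasome subunit, had the highest value, with a log2 difference of 0.28 (SE 0.11) in light against dark, from a mean of -0.20 over the reference in the dark to 0.081 in light. phoU stood at 0.26 (SE 0.075), panB at 0.24 (SE 0.076) and purF, the first enzyme of purine synthesis, at 0.19 (SE 0.076). The lowest were pheA, prephenate dehydratase, at -0.24 (SE 0.086), pan1 at -0.20 (SE 0.091) and ileS, isoleucyl-tRNA synthetase, at -0.16 (SE 0.076). The replication initiator gene orc7, which the naming rule also picked, stood at -0.20 (SE 0.086) and was above background on 4 of 8 arrays in the strain's channel. All 8 missed the threshold, with limma adjusted p of 0.816 to 0.841.

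In the chaperone and proteasome list 4 of 5 genes had positive differences, with a median of 0.091, and 0 passed, also when adjusted over the list alone. The annotation gives no product for panB, a list member whose symbol is also used for a pantothenate enzyme, and pan1 lies outside the list. camera gave an adjusted p of 0.279 for this list and for DNA repair, where 3 of 4 were negative. The 4 cobalamin genes were all negative, with a median of -0.071 and an adjusted p of 0.519. The phototrophy list, which holds the rhodopsin genes hop, sop1 and sop2 and the regulator bat, had 3 of 4 positive values with a median of 0.060, 0 past the threshold and an adjusted p of 0.623. TCA cycle, motility and chemotaxis, nucleotide synthesis and amino acid synthesis genes had medians of -0.0041, 0.029, -0.0048 and -0.027. Of the lists too small for camera, phoU passed when adjusted over the list alone, as the single member of phosphate uptake, and so did 1 of the 2 genes of the DMSO and TMAO respiration list, the dim moaA. Only moaA and moaC of that list were measured, so it says little about the pathway.

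For light, 0 of 2688 features passed in limma, with a smallest adjusted p of 0.768, and 157 lay at an unadjusted p under 0.05 against 134.4 by chance, 4 of them named genes. The authors' value table gave 49 features for light, among them psmA, phoU and panB, higher in light, and the dim mutL and mamA. It also put the chaperone and proteasome list past the threshold, with 5 of 5 genes positive, a median of 0.15 and an adjusted p of 0.0244 in camera with the preset correlation, against an adjusted p of 0.956 with an estimated correlation. The latter rests on 1 residual degree of freedom and could hardly pass any list. moaA and mutL, also picked by the naming rule, were below background in both channels on all arrays and are given no value.

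The interaction asks whether the oxygen difference depends on light, which with 1 sample per combination can be described only. Among the genes above, purL differed by -0.21 between high and low oxygen in light and by -0.21 in the dark, gyrA by 0.15 and 0.14, and serS by -0.32 and -0.26. carB differed by -0.19 in light and by -0.44 in the dark, and psmA by -0.041 and 0.24. Across all features the oxygen difference in light correlated with that in the dark at r = 0.16 (Spearman's rho 0.24), and among the 672 brightest at r = 0.51 (rho 0.45). The light difference in high oxygen correlated with that in low oxygen at r = 0.010 across all features and at 0.18 among the brightest, and among the brightest it was negative from the Alexa 532 arrays alone (-0.078) and from the L scan alone (-0.065). These comparisons share no array. From the L scan alone, the correlation of the oxygen differences among the brightest features was 0.017.

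**Figure D2:**
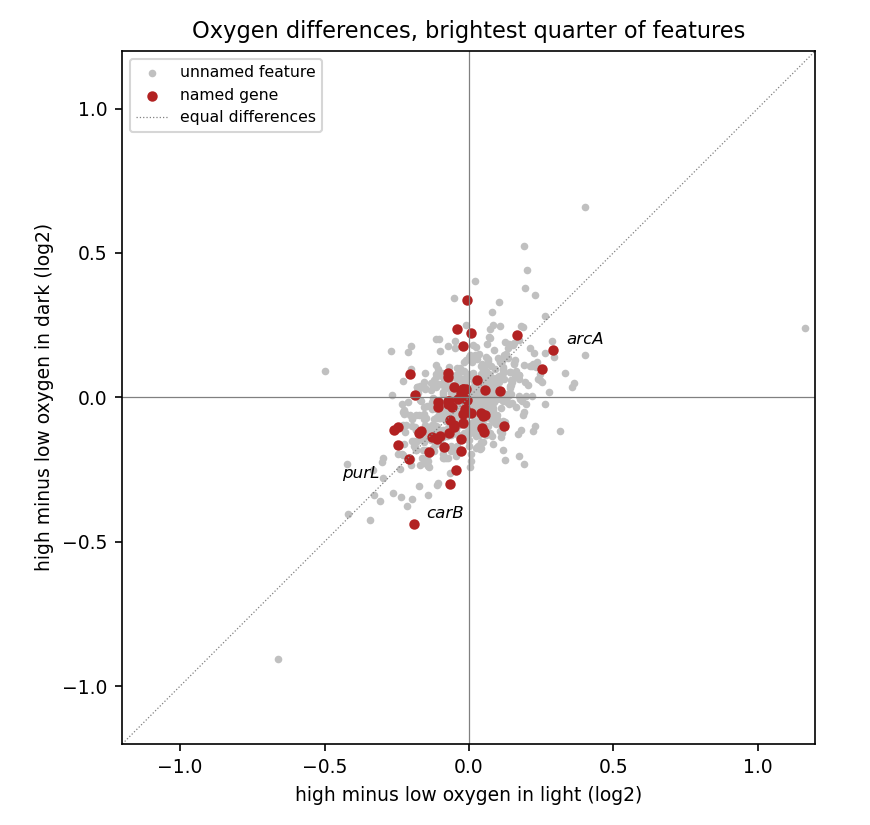
Log2 difference between high and low oxygen in light (horizontal axis) and in the dark (vertical axis) for the 672 brightest features, 614 unnamed (grey) and 58 named (red), each the difference of 2 RNA samples. Points spread along the dotted line of equal differences (r = 0.51), with carB and purL on the negative side and arcA on the positive side of both axes.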

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

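The tests of explanations in this part were chosen after the results were seen. Over the 32 genes picked by the naming rule and both factors, 5 of 64 pairs of differences went one way on both arrays of one group and the other way on both arrays of the other group. Of the 64 pairs, 20 were picked for the same sign in all 4 differences and could not be flagged. Independent signs would give 5.5 among the other 44, but the 2 arrays of a group share 1 RNA sample, so their signs are not independent. The difference between the groups was not tested in any of them, since each combination has 1 sample. For pyrF the oxygen difference was negative in light and positive in the dark, and its light difference negative in high and positive in low oxygen, with 1 gap of -0.77 for both. The bat light difference was positive in high and negative in low oxygen, a gap of 0.39. Both pyrF and bat were near or below background, so these gaps do not measure a response. For gdhB the light difference was -0.15 in high and 0.042 in low oxygen, a gap of -0.19, and for carB it was 0.12 and -0.13, a gap of 0.25.

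The strain differed from the reference in 401 features. Dye bias as the whole cause would give features picked on one dye orientation the opposite sign in the other. Of the 447 features called from the Alexa 532 arrays alone, 74.3% had the same sign on the Alexa 647 arrays. Of as many with the largest t on the Alexa 647 arrays, 69.4% had the same sign on the others. Among all features, picked or not, 59.6% had the same sign in both dye orientations. Dye bias is thus argued against as the whole cause, but the picked features that changed sign stay open to it. A dye effect that is the same on every array also cancels in the mean of 2 exchanged arrays. Noise of spots near background is argued against as the whole cause by calls being 3.15 times as frequent among features above background on all 8 arrays (24.9% of 952) as among those above it on none (7.90% of 1063). Part of the calls stays open to it, with 84 of the 401 in features above background on no array in the strain's channel. The growth state of the reference culture instead of the strain stays open, since there is 1 reference RNA preparation and it was not grown in the conditions of the samples. The lower ribosomal protein genes and the higher arginine fermentation genes may therefore belong to the deletions or to the culture.

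Oxygen differences were alike in light and dark among bright features (r = 0.51). Dye-linked drift over the arrays would make the differences from the opposite dye orientations oppose each other, and they correlated at r = 0.30. Defects at fixed places of the slides are argued against as the whole cause, because taking the light difference from one spot copy and the dark difference from the other gave r = 0.29, against 0.37 within 1 copy. Array order stays open, as the order of array numbers holds 2 runs, all high oxygen arrays and then all low oxygen arrays. A response to oxygen in this strain is the biological candidate and could not be separated from it.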

How the results depend on the processing

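Chosen after seeing the data were the fit with a dye term, the H or L scan alone, loess per block, the fits to bright features, median centring without background subtraction, the gene list test against the reference with its alternatives, the gene lists against all features, and the estimated correlation for values without background subtraction or loess. The others were chosen before. The oxygen and light comparisons gave 0 features in all alternatives not named below, and the 0 counts with each array or sample left out come from fits whose lone samples are assumed to vary like the rest. Where no cause is named, the cause was not tested. Dim features limit the ratios: 1063 of 2688 were above background on no array.

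For features that differ from the reference (401), the count was 844 without background subtraction, 1172 in the authors' value table, 1209 without background subtraction and with median centring, 1351 from 8 arrays with the sample as a random block and 1239 with a dye term added. It was 850 at an adjusted p of 0.1, 3 with a log2 ratio of at least 1, and 262 among the 672 brightest features, where fewer were tested. From the arrays with the strain in Alexa 647 it was 0, and 447 from those in Alexa 532. Leaving out 1 array gave 0 to 608, with 0 without high oxygen dark replicate 1 or low oxygen dark replicate 1, 145 without high oxygen light replicate 1 and 608 without low oxygen dark replicate 2. Among the 672 brightest features the count also depended on the variance prior. With limma's trend and robust options it was 485 of these 672. The other alternatives gave 332 to 528, some of them out of fewer than 2688 features. The block correlation of the 8 arrays was -0.63, and -0.39 with a dye term. A negative value narrows the SE in these fits, which also count technical copies as separate arrays. How far this made their higher counts was not tested. Replicate numbers mark the dye orientation of 2 arrays of 1 RNA sample, so a block on the number is the dye term and pairs no cultures.

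For oxygen and light, the value table gave 117 and 49 features, median centring without background subtraction 129 and 61, the random block 70 and 12, with a dye term 1 and 0, and the L scan 6 and 4. The first 2 settings also put 1 list past the threshold for light, chaperones and proteasome, and 0 for oxygen. With an estimated correlation this list did not pass camera in either setting (adjusted p = 0.956 and 0.942). That form of camera rests on 1 residual degree of freedom, so hardly any list could pass it. The 2 lists that differed from the reference became 0 with an estimated correlation and 1 with fry, which does not compare a list with other genes and picked the phototrophy list (adjusted p = 0.0386).

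The correlation of oxygen differences in light and dark over all features (0.16) was 0.34 without background subtraction, 0.20 with median centring, 0.36 with both, 0.38 in the value table, 0.38 without the dimmest features, 0.33 and 0.51 in the 1344 and 672 brightest, 0.11 from the arrays with the strain in Alexa 532, 0.0099 from the L scan, and 0.036 to 0.20 with 1 array left out. Among the 672 brightest (0.51) it was 0.42 from the arrays with the strain in Alexa 532, 0.34 from those in Alexa 647, 0.017 from the L scan, and 0.35 to 0.51 with 1 array left out. For light differences there (0.18) it was 0.28 in the value table, 0.27 with median centring and no background subtraction, 0.10 from Alexa 647, negative at -0.078 from Alexa 532 and -0.065 from the L scan, and 0.021 to 0.24 with 1 array left out.

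The pyrF ratio to the reference (-0.51) was negative in all 22 alternatives, and limma's adjusted p ran from 1.44e-10 to 0.105. It passed without background subtraction (-0.27), in the value table (-0.29), with median centring and no background subtraction (-0.27), with the random block with or without a dye term (-0.51), from Alexa 532 alone (-0.47) and from the L scan (-0.32), and ran from -0.58 to -0.43 with 1 array left out, past the threshold without high oxygen light replicate 2, low oxygen light replicate 2 or low oxygen dark replicate 2 (adjusted p = 0.0386, 0.0375 and 0.00920). Of 1530 values of named genes under alternatives, 27 changed sign, 16 of them of the dim pyrF and bat and none that had passed the threshold. The pyrF oxygen difference became 0.097 without background subtraction, 0.047 with median centring, 0.049 in the value table, 0.0015 with median centring and no background subtraction and 0.21 from Alexa 532, and ran from -0.33 to 0.29 with 1 array or sample left out. Its light difference was 0.16 from the L scan. The bat ratio was -0.065 from Alexa 532, its light difference -0.025 in the value table and -0.044 to 0.25 with 1 array or sample left out, and its oxygen difference -0.030 from the L scan and -0.047 to 0.25 with 1 left out. From the L scan, the light difference was -0.031 for panB and 0.022 for orc7. Of ratios to the reference that had not passed, sdhC became -0.010 in the value table, -0.011 with median centring and no background subtraction, -0.11 with loess per block and -0.023 from Alexa 532, where hop became -0.099 and sop1 -0.078. sop2 became 0.087 from Alexa 647 and 0.037 from the L scan, where icd became 0.051.

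Of the named calls against the reference, those of arcC, rpmC, rpl12p and sucC held in 22 of 25 alternatives and those of lysS and gyrA in 20 of 23, and each was lost only from Alexa 647 and without high oxygen dark replicate 1 or low oxygen dark replicate 1. argH, cbiT and purL held in 21 of 25, sucD and speB in 20, gdhB in 18, phoU in 17, secY in 16, and arcA and gdhA1 in 14, with pan1 in 17 and gdhA2 in 16 of 23, htr4 in 13 of 22 and gatC in 12 of 21. These alternatives include both fits with arrays as units.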

Other observations

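The list of aminoacyl-tRNA synthetases, the amino acid synthesis list without them, the tests of lists against the reference and the tests of explanations were chosen after the results were seen. The aminoacyl-tRNA synthetases, set apart as a list of 12 genes, had 10 negative log2 ratios against the reference with a median of -0.083, and 1 passed the threshold, lysS, also when adjusted over the list alone (camera adjusted p = 0.471). Their oxygen differences were negative for 10 of 12 genes, with 0 past the threshold, and camera gave an adjusted p of 0.233. The amino acid synthesis list without them had 8 of 12 positive ratios against the reference and an adjusted p of 0.0992, with argH its 1 gene past the threshold. Of the remaining small lists, aerobic respiration (nuoL at -0.036), metal and iron uptake (phnE at -0.14), glycerol metabolism (glpK, below background on all arrays) and oxidative stress (msrA and dpsA, median 0.14) had 0 genes past the threshold against the reference. When adjusted over the list alone, phnE passed as the single measured gene of its list, where no adjustment takes place. So did 1 gene of oxidative stress and 1 of 2 of DMSO and TMAO respiration.

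The authors' value table gave 117 features for oxygen, 72 higher and 45 lower, where the loess values gave 0. An intensity-linked shift between the dyes, which the value table keeps (Spearman's rho of the oxygen effect with intensity -0.50, against -0.058 after background subtraction and loess), could have made these differences. Adding loess alone, both without background subtraction, left a median share of 0.927 of the difference in the 117 features (quartiles 0.804 and 1.04), with 117 keeping their sign, so the shift is argued against as the source of the differences. The same step took the oxygen calls from 129 to 0 while the median SE of the 117 features went from 0.077 to 0.062 in log2, and the degrees of freedom of limma's prior went from 841.5 to 4.75. A variance estimate shared more firmly across features, through more prior degrees of freedom, is the candidate that remains. The variance itself was not smaller, with a prior SD of 0.077 for the median-centred values against 0.062 with loess. The exchanges of priors below changed both together. With the prior of the loess values, the median-centred values without background subtraction gave 1 feature for oxygen and 958 of 1209 against the reference, and with the prior of the median-centred values the loess values gave 74 for oxygen. The value table with the prior of the loess values without background subtraction gave 1 feature for oxygen, 0 for light and 930 of 1172 against the reference. The prior of the loess values after background subtraction had 2.27 degrees of freedom and an SD of 0.089. With it the value table gave 0 in all 3 comparisons, so that prior does not single out oxygen. Whether the shift itself brought about that prior was not tested. The oxygen differences of carB, serS, glmS, gdhA1 and glyA were -0.31, -0.26, -0.24, -0.25 and -0.25 in the value table and -0.31, -0.29, -0.27, -0.21 and -0.19 after background subtraction and loess.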
